A study of Homo sapiens with 40 samples.

How the data were processed

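Total RNA from U2OS cells carrying a doxycycline-inducible MYC gene was sequenced as 40 libraries, with 4 libraries in each of 10 groups. The groups combine 2 treatments (Dox at 1 µg/ml or EtOH, 24 h) with 5 hairpins, and cells carrying the vector were kept in puromycin at 0.2 µg/ml, per the labels. The values are read counts per gene, deposited as 1 table per library with no further scaling that the headers or values show. Per the submitters' processing notes the tools were Bowtie, HISAT2 and edgeR and the genome build was hg19. The notes give no versions, and the role of each tool, the strand setting, the counting program and the annotation are not given in the sources used here. For that reason no coordinates are printed.

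Each table lists 63545 entries, of which 393 are LRG entries with 0 reads and 63152 are Ensembl genes. Symbols from the reference annotation were found for 39560 genes, which hold 97.27% of the reads. Totals ran from 877323 to 1532617 counts with a median of 1213230.5. The mitochondrially encoded genes are listed at 0 in every library and markers of blood cells did not reach the filter, so these lists gave no value.

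Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with the filter of edgeR by group (a count of at least 10 in the library of median size and 15 in all), which left 12557 genes with 98.65% of the reads. Library sizes were scaled by TMM, with factors from 0.9226 to 1.029. A single quasi-likelihood model with robust estimation and a mean for each of the 10 groups was fitted to all 40 libraries. Its common dispersion was 0.01290, a coefficient of variation of 11.36%, with 30 residual and a median of 18.75 prior degrees of freedom. Changes of a knockdown are contrasts that average its 2 hairpins. P-values are two-sided and were adjusted by Benjamini-Hochberg over the genes tested, at a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Fitted fold changes use the default prior count of edgeR. A prior count of 2 was used only for the log2 CPM behind slopes and correlations between libraries. CPM values use the scaled library sizes and SD is over the 4 libraries of a group. The p-values measure spread between libraries, which may be partly technical, since the labels give only replicate numbers. The deposited names also carry a letter, A or B, and a digit, whose meaning is not given. Whether the libraries of a group come from separate cultures is therefore not known.

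The comparisons were Dox against EtOH in shNTC, shCTR9 and shCDC73 cells, each knockdown against shNTC in each treatment, and the difference of the Dox response between each knockdown and shNTC. The knockdowns were also compared with each other and the hairpins against each target with each other, in each treatment. For 27 gene lists with 765 entries, of which 612 were tested, camera was run with a preset correlation of 0.01 and again with an estimated one, and fry beside it. Adjustment was over the lists within a comparison. The lists cover ribosome biogenesis, common MYC targets, MYC-repressed genes, nucleotide synthesis, glycolysis, tRNA synthetases, ribosomal proteins of both kinds, DNA replication, G2 and M phase, DNA repair and histones. They also cover p53, ATF4, unfolded protein, heat shock, interferon, NF-kB, immediate early, matrix and cholesterol genes, elongation factors, the PAF1 complex and markers of osteoblast, epithelial and blood cells. A list of cleavage-stage genes was added after the data had been seen and is used in the closing section only.

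The choice of comparisons, tests, lists, named genes and alternatives, except those stated as added, was made before the data were examined. Genes were named by a rule. It takes MYC and the PAF1 complex subunits, the 10 largest changes each way per comparison (5 for differences of response and between knockdowns) among genes with a mean of at least 2 CPM, and the 4 members of each list with the smallest p. Outside the differences of response the largest changes also had to separate every treated library from every control and to pass with each hairpin alone. Some genes the rule allows are not reported.

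Genes for the test of the Dox response as a whole were chosen in the other knockdown and tested with fry, and their median difference is given. The overlap of the knockdowns was set beside simulations of unchanged groups with shared controls and beside splits of the shNTC libraries. Replicates of a group were compared by a chi-square over genes, with values per degree of freedom from 1.06 to 9.04, so no pair of libraries was within sampling noise.

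The analysis was tested on simulated counts. For Dox in shNTC cells it recovered 28.4%, 77.6% and 95.5% of genes changed by 1.5-fold, 2-fold and 4-fold, and called 6 of 12260 unchanged genes. For shCTR9 against shNTC in EtOH the shares were 49.3%, 76.1% and 97.0%. For the difference of the Dox response in shCTR9 cells they were 22.4%, 61.2% and 93.9%. Of 26 unmoved lists 0 were called by camera with either correlation or by fry. Simulated genes were drawn independently, so this does not cover list calls that arise from correlation between genes.

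Alternatives were RLE size factors, no filter, a filter at a mean of 1 CPM, a replicate block, sums of libraries sharing a letter in their names, limma-voom with quality weights, the Wald test of DESeq2 1.42.0, leaving out each replicate number and each library, only the groups compared and each hairpin alone. For the Dox response as a whole, genes were also chosen at 1.5-fold and in a part of the shNTC libraries. After the data had been seen, a fit without the 3 libraries that stand apart on transcript length and a fit with the transcript-length slope of each library as a covariate were added.

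Other splits of the libraries were counted for each comparison. With 4 libraries against 4 all 35 splits were used, and otherwise 100 including the real one. For Dox in a knockdown the treatment was permuted within each hairpin, for the other 2-group comparisons all libraries of the comparison were drawn from, and for differences of response the 12 Dox libraries were split into 8 and 4 with the shRNA and treatment terms kept. A first scheme, which exchanged labels among all 3 shRNAs, was replaced after its first results were seen because it let the effect of a knockdown enter the contrast. The real values beside the splits come from fits of the groups compared alone with fewer terms than elsewhere. Both hairpins of a knockdown shared 1 mean in comparisons of 2 conditions, and 1 Dox response, with a mean per hairpin, in those on Dox. These counts therefore differ from those of fits with a mean per group. For the slopes on gene span, knockdown and shNTC labels were also permuted within each treatment, 100000 times.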

Results

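Total RNA was sequenced from U2OS cells, a human osteosarcoma line, carrying a MYC gene that doxycycline (Dox) switches on. The cells expressed short hairpin RNAs from a pGIPZ vector. These were a control hairpin labelled shNTC, hairpins 3 and 5 against CTR9 (shCTR9), and hairpins 3 and 4 against CDC73 (shCDC73). CTR9 and CDC73 are subunits of the PAF1 complex, which travels with elongating RNA polymerase II. Cells were given Dox at 1 µg/ml or ethanol (EtOH) for 24 h, which makes 10 groups of 4 libraries, 40 libraries in all. Each library was measured as a read count per gene, and the library totals ran from 877323 to 1532617 counts. Levels are given as CPM, the count of a gene scaled to the total of its library. A count of 3, the floor used here for a gene with no reads, equals 3.42 CPM in the shallowest library and 1.96 CPM in the deepest. Floors cover counting error only.

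Changes are given as log2 fold changes ± their standard error. A gene is said to rise or fall where its adjusted p from the quasi-likelihood test of edgeR is under 0.05 among the 12557 genes tested. A list of genes fixed in advance is said to do so where the adjusted p of the camera test is under 0.05. Changes in shCTR9 or shCDC73 cells are averages over the 2 hairpins, so they rest on 8 libraries against 4 of shNTC, or on 8 against 8 for Dox within a knockdown. Genes named for the size of their change lay on the same side of their controls in every library and passed the test with each hairpin alone. In 3 libraries, short transcripts were read more often than in the others. The slope of a gene's deviation on its log2 transcript length was -0.118 and -0.158 in EtOH shCDC73 hairpin 4 replicates 1 and 3 and -0.152 in EtOH shCTR9 hairpin 3 replicate 1. In the other libraries it lay between -0.037 and 0.046.

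The first question was whether each hairpin lowered its target. CTR9 (ENSG00000198730) stood at 73.9 ± 4.89 CPM (SD, n = 4) in shNTC cells in EtOH. With shCTR9 hairpins 3 and 5 it stood at 20.5 ± 2.91 and 20.1 ± 1.91 CPM, which is 27.7% and 27.2% of the control. CDC73 (ENSG00000134371) stood at 35.6 ± 6.68 CPM (SD, n = 4) in shNTC cells. With shCDC73 hairpins 3 and 4 it stood at 8.03 ± 1.44 and 8.20 ± 2.67 CPM, which is 22.6% and 23.0%. In Dox CTR9 was at 26.6% and 23.5% of the shNTC level and CDC73 at 22.3% and 32.4%. Every knockdown library lay below every shNTC library of its treatment. The averaged falls in EtOH were -1.87 ± 0.11 for CTR9 (adjusted p = 4.03e-19) and -2.12 ± 0.19 for CDC73 (adjusted p = 3e-13).

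Loss of CDC73 raised CTR9. In shCDC73 cells CTR9 rose by 1.18 ± 0.09 in EtOH (adjusted p = 2.33e-15) and by 0.92 ± 0.09 in Dox (adjusted p = 5.1e-12). Its level reached 183 ± 8.79 and 154 ± 9.11 CPM with hairpins 3 and 4 in EtOH (SD, n = 4). The reverse did not pass the test, with CDC73 changing in shCTR9 cells by -0.28 ± 0.15 in EtOH (adjusted p = 0.137) and by 0.11 ± 0.16 in Dox (adjusted p = 0.614). Without EtOH shNTC replicate 1 the change in EtOH was -0.40 and passed (adjusted p = 0.0429). Among the other subunits RTF1 rose by 0.54 ± 0.11 in shCDC73 cells in EtOH (adjusted p = 3.33e-05). In shCTR9 cells it changed by 0.31 ± 0.11 (adjusted p = 0.015), a call that ended with hairpin 5 alone (adjusted p = 0.305) and without EtOH shNTC replicate 4 (adjusted p = 0.0527). It also ended without replicate 3 or 4 of every group (adjusted p = 0.0619 and adjusted p = 0.0846). In Dox RTF1 rose by 0.33 ± 0.11 in shCTR9 and 0.46 ± 0.11 in shCDC73 cells (adjusted p = 0.00985 and adjusted p = 0.000403) and passed with each hairpin alone. In shCTR9 cells this ended without replicate 3 of every group (adjusted p = 0.0523). PAF1 itself was called higher, in EtOH by 0.35 ± 0.13 and 0.46 ± 0.13 in shCTR9 and shCDC73 cells (adjusted p = 0.0234 and adjusted p = 0.00283) and in Dox by 0.43 ± 0.13 and 0.40 ± 0.13 (adjusted p = 0.00727 and adjusted p = 0.0121). These calls ended with 1 of the hairpins alone in each case, with shCTR9 hairpin 5 (adjusted p = 0.159 in EtOH and adjusted p = 0.168 in Dox), shCDC73 hairpin 3 in EtOH (adjusted p = 0.097) and shCDC73 hairpin 4 in Dox (adjusted p = 0.146). In shCTR9 cells in EtOH that of PAF1 also ended without replicate 1, 2 or 3 of every group (adjusted p = 0.102, adjusted p = 0.0975 and adjusted p = 0.067), without EtOH shNTC replicate 1 or 3 (adjusted p = 0.109 and adjusted p = 0.0683) and without EtOH shCTR9 hairpin 5 replicate 2 (adjusted p = 0.0521). In Dox it ended without Dox shNTC replicate 3 in both (adjusted p = 0.0536 and adjusted p = 0.0774), in shCTR9 cells without replicate 2 of every group (adjusted p = 0.0512), and in shCDC73 cells without replicate 1 or 3 (adjusted p = 0.0623 and adjusted p = 0.167). LEO1 changed by 0.58 ± 0.32 and 0.48 ± 0.32 in EtOH in shCTR9 and shCDC73 cells (adjusted p = 0.135 and adjusted p = 0.217). Without EtOH shNTC replicate 4 these were 0.98 (adjusted p = 0.0258) and 0.89 (adjusted p = 0.0438). In shCTR9 cells LEO1 also passed without replicate 4 of every group (1.01, adjusted p = 0.0375). The list of 6 PAF1 complex genes did not pass in any comparison against shNTC or with Dox (adjusted p from 0.376 to 0.893).

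MYC (ENSG00000136997), the transcription factor under study, was switched on in every group. In shNTC cells it went from 509 ± 68.2 to 14945 ± 667 CPM (SD, n = 4 in each group), a rise of 4.88 ± 0.09 (adjusted p = 5.83e-42). It rose by 4.09 ± 0.06 in shCTR9 cells (adjusted p = 2.64e-46) and by 4.00 ± 0.06 in shCDC73 cells (adjusted p = 6.85e-46). The tests of the difference gave -0.78 ± 0.09 for shCTR9 (adjusted p = 3.13e-07) and -0.88 ± 0.09 for shCDC73 (adjusted p = 9.05e-09). In Dox the MYC level was lower than in shNTC cells with each of the 4 hairpins. It stood at 77.4% and 62.8% of that level with shCTR9 hairpins 3 and 5 and at 71.8% and 55.5% with shCDC73 hairpins 3 and 4. In EtOH the averaged change of MYC was 0.26 ± 0.07 in shCTR9 cells (adjusted p = 0.00107) and 0.22 ± 0.07 in shCDC73 cells (adjusted p = 0.00593). These calls ended with shCTR9 hairpin 5 alone (adjusted p = 0.268), with shCDC73 hairpin 4 alone (adjusted p = 0.693) and without replicate 4 of every group (adjusted p = 0.0737 and adjusted p = 0.0976). In shCDC73 cells the call also ended without replicate 3 of every group (adjusted p = 0.0546), without EtOH shNTC replicate 3 or 4 (adjusted p = 0.0556 and adjusted p = 0.071) and with only the groups compared (adjusted p = 0.0706). Counts per gene do not separate transcripts of the inducible gene from those of the cells' own MYC.

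**Figure D1:**
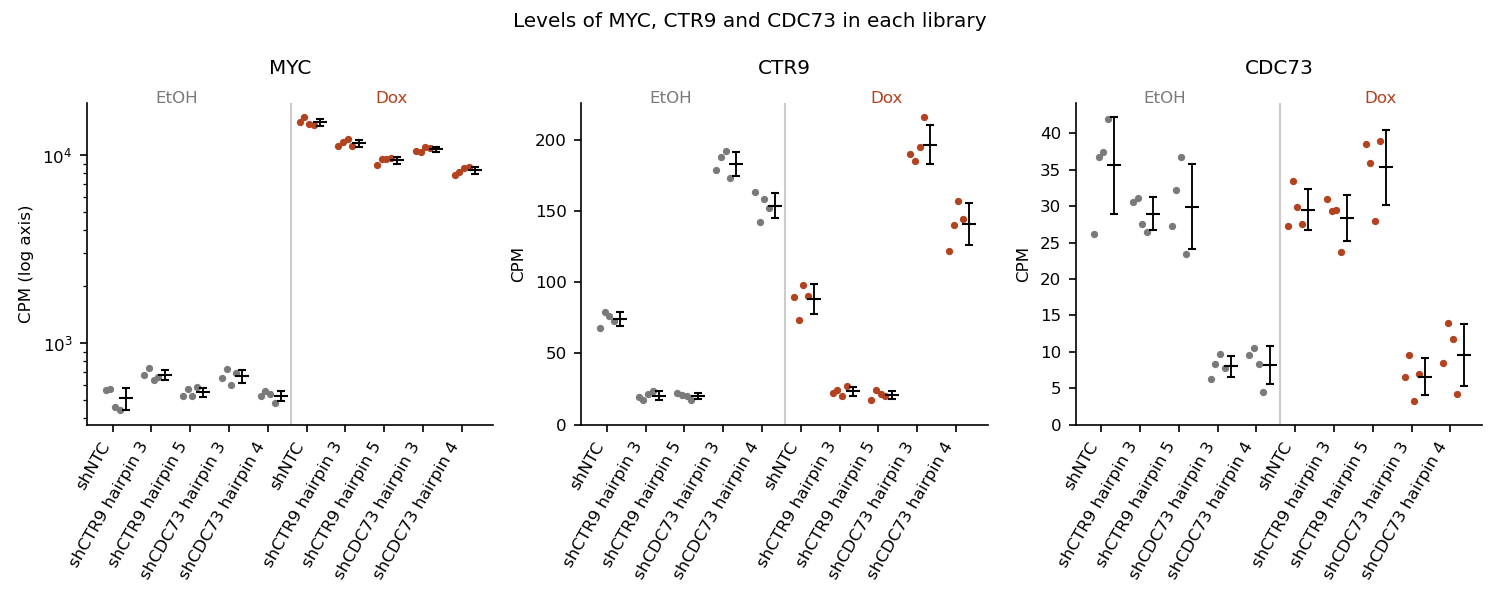
CPM of MYC (log axis), CTR9 and CDC73 in each of the 40 libraries, by treatment and hairpin, where points are libraries and black marks give the mean and SD of the 4 libraries of a group. CTR9 lay at 20.5 and 20.1 CPM with its own hairpins in EtOH and at 183 and 154 CPM with the hairpins against CDC73.

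The next comparison asked what Dox, which switches on MYC, did in control cells. In shNTC cells Dox raised genes that build ribosomes and that respond to amino acid stress, and lowered genes of mitosis and of the extracellular matrix and cytoskeleton (n = 4 libraries per group). Of 46 ribosome biogenesis genes tested 28 rose and 0 fell, or 33 and 0 adjusted over the list alone (camera adjusted p = 2.92e-16). They included the nucleolar scaffold gene NOLC1 at 0.56 ± 0.08, RRP12 at 0.64 ± 0.09 and RRP9 at 1.04 ± 0.16. Of 24 targets of the stress regulator ATF4, 9 rose and 0 fell, or 13 and 0 adjusted over the list alone (adjusted p = 6.35e-07). Among them were ATF3 at 0.98 ± 0.13, TRIB3 at 1.15 ± 0.17 and the amino acid transporter gene SLC7A5 at 0.72 ± 0.11. HK2, which encodes the glycolytic enzyme hexokinase 2, rose by 1.26 ± 0.11 and the cyclin gene CCND2 by 0.78 ± 0.08. The largest rises outside these lists included KLF15 at 3.65 ± 0.49, a zinc finger factor gene, and CAMKV at 2.72 ± 0.19. EGR1, an immediate early transcription factor gene, rose by 2.82 ± 0.18 (adjusted p = 4.17e-17).

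Genes of cell division and of the matrix fell with Dox in shNTC cells. None of 34 genes of the G2 and M phases rose and 22 fell, or 24 adjusted over the list alone (adjusted p = 1.35e-11). Among them were the topoisomerase gene TOP2A at -0.66 ± 0.08, NUF2 of the kinetochore at -0.90 ± 0.15 and the mitotic kinesin gene KIF20A at -0.65 ± 0.12. Of 30 TGF-beta, matrix and cytoskeleton genes 16 fell and 0 rose, or 18 and 0 adjusted over the list alone (adjusted p = 2.3e-15). Examples were TGFBI at -0.96 ± 0.10 and the tropomyosin gene TPM1 at -1.29 ± 0.15. Of 17 genes known to be repressed by MYC, 9 fell and 1 rose, or 11 and 1 adjusted over the list alone (adjusted p = 1.31e-06), with SPARC at -0.62 ± 0.08 and THBS1 at -0.91 ± 0.13. Of 40 DNA replication and E2F target genes 10 fell and 2 rose, or 12 and 2 adjusted over the list alone (adjusted p = 0.00972). RRM2, a subunit of ribonucleotide reductase, fell by 0.67 ± 0.08 and ASF1B, a histone chaperone gene, by 1.10 ± 0.16. Of 7 osteoblast and mesenchymal markers 4 fell and 0 rose, with the same counts adjusted over the list alone (adjusted p = 0.00347). They included VIM at -0.70 ± 0.12 and COL1A1 at -0.82 ± 0.16.

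In all, Dox in shNTC cells raised 1066 genes and lowered 1121, of which 1181 changed by at least 1.5-fold. Of 19 immediate early genes 7 rose and 3 fell, or 8 and 5 adjusted over the list alone (adjusted p = 6.25e-11), but this list holds MYC itself. The calls for 3 lists were lost with an estimated correlation. Of 42 common MYC targets 8 rose and 2 fell, or 9 and 3 adjusted over the list alone (adjusted p = 0.00432, and adjusted p = 0.366 with an estimated correlation). Of 35 mitochondrial ribosomal proteins 5 rose and 0 fell, or 3 and 0 adjusted over the list alone (adjusted p = 0.0369, and adjusted p = 0.564 with an estimated correlation). Of 22 cholesterol synthesis genes 0 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.0434, and adjusted p = 0.101 with an estimated correlation). The cholesterol call also ended without replicate 1 (adjusted p = 0.0526) or 4 (adjusted p = 0.137) of every group, over alternatives from 0.00792 to 0.137.

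Other lists did not pass with Dox in shNTC cells. Purine and pyrimidine synthesis had 7 members that rose and 3 that fell of 25 (adjusted p = 0.396). The counts were 3 and 1 of 20 for aminoacyl-tRNA synthetases (adjusted p = 0.254), 4 and 5 of 23 for glycolysis (adjusted p = 0.437) and 4 and 5 of 29 for p53 targets (adjusted p = 0.415). They were 1 and 5 of 14 for interferon-stimulated genes (adjusted p = 0.191), 3 and 1 of 14 for NF-kB and inflammatory genes (adjusted p = 0.893) and 3 and 1 of 13 for heat shock genes (adjusted p = 0.127). Double-strand break repair had 1 and 3 of 38 (adjusted p = 0.683), replication-dependent histones 3 and 1 of 12 (adjusted p = 0.437) and elongation factors 4 and 0 of 30 (adjusted p = 0.291). The 48 cytoplasmic ribosomal protein genes had a median of -0.05 (adjusted p = 0.437). The unfolded protein response had 1 and 3 of 20 (adjusted p = 0.396) and epithelial markers of other cells 0 and 1 of 4 (adjusted p = 0.396). Without replicate 2, 3 or 4 of every group the count of genes called was 1344, 1378 or 1303.

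**Figure D2:**
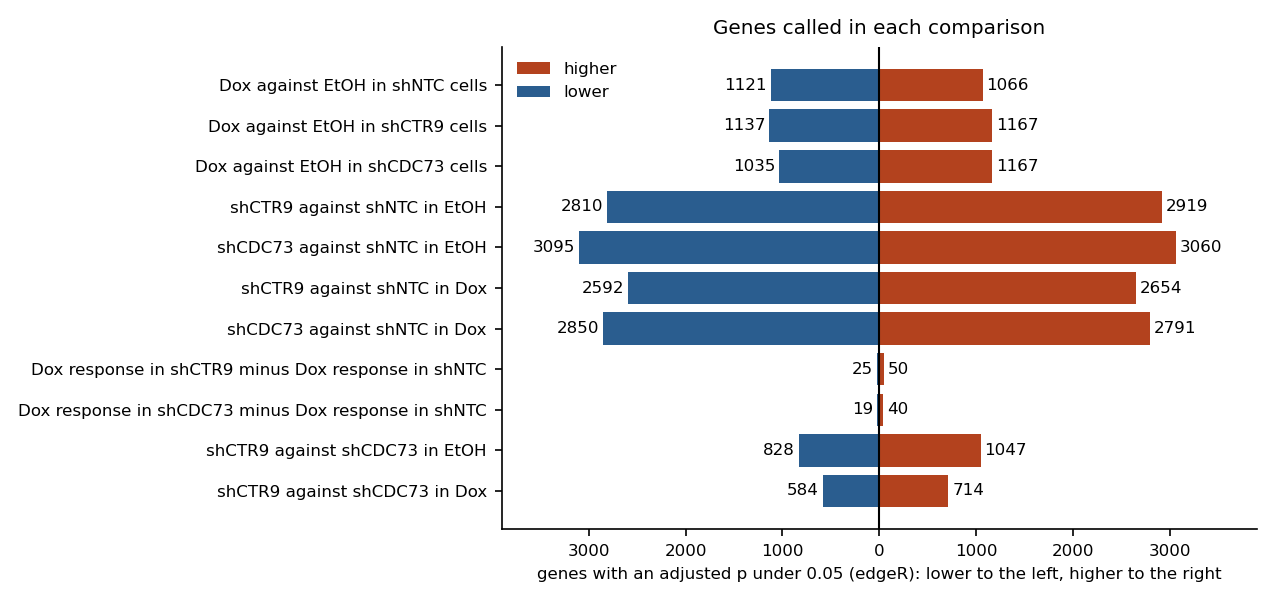
Number of genes with an adjusted p under 0.05 in each comparison, higher to the right and lower to the left of 0, where knockdown bars are averages over the 2 hairpins. Against shNTC in EtOH, 2919 genes were higher and 2810 lower in shCTR9 cells and 3060 higher and 3095 lower in shCDC73 cells.

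The same treatment was then compared within the knockdown cells (8 libraries against 8). Dox again raised ribosome biogenesis genes. In shCTR9 cells 22 of 46 rose and 0 fell, or 25 and 0 adjusted over the list alone (adjusted p = 1.69e-09). In shCDC73 cells 27 rose and 0 fell, or 33 and 0 adjusted over the list alone (adjusted p = 2.13e-15). NOP2, an rRNA methyltransferase gene, rose by 0.48 ± 0.07 and 0.50 ± 0.07, and HK2 by 1.29 ± 0.08 and 1.40 ± 0.08, in shCTR9 and shCDC73 cells. Heat shock genes rose as a list in both. In shCTR9 cells 8 of 13 rose and 0 fell, or 9 and 0 adjusted over the list alone (adjusted p = 6.68e-08). In shCDC73 cells 7 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 8.55e-06). The co-chaperone gene BAG3 rose by 0.45 ± 0.07 and 0.36 ± 0.07 in shCTR9 and shCDC73 cells. HSPA6, an inducible HSP70 gene, had log2 fold changes of 4.59 ± 0.15 in shCTR9 cells and 4.17 ± 0.15 in shCDC73 cells. Close relatives of HSPA6 share much of its sequence, so the gene its reads come from is uncertain.

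ATF4 targets and immediate early genes also rose with Dox in both knockdowns. Of 24 ATF4 targets 8 rose and 1 fell in shCTR9 cells, or 10 and 1 adjusted over the list alone (adjusted p = 0.0032). In shCDC73 cells 8 rose and 0 fell, or 9 and 0 adjusted over the list alone (adjusted p = 0.0023), and SLC7A5 rose by 0.64 ± 0.08 and 0.71 ± 0.08. In the immediate early list, which holds MYC, 7 rose and 3 fell of 19 in shCTR9 cells, or 8 and 3 adjusted over the list alone (adjusted p = 1.65e-11). In shCDC73 cells 6 rose and 2 fell, or 7 and 2 adjusted over the list alone (adjusted p = 5.37e-14), and FOS rose by 0.97 ± 0.11 and 1.01 ± 0.11.

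Matrix, mitotic and MYC-repressed genes fell with Dox in both knockdowns. Of 30 TGF-beta, matrix and cytoskeleton genes 12 fell in shCTR9 cells, or 13 adjusted over the list alone (adjusted p = 1.48e-06). In shCDC73 cells 8 fell, or 9 adjusted over the list alone (adjusted p = 2.81e-06), and TGFBI fell by 0.91 ± 0.08 and 0.76 ± 0.08. Of 34 G2 and M phase genes 9 fell in shCTR9 cells, or 10 adjusted over the list alone (adjusted p = 0.00251). In shCDC73 cells 7 fell, also adjusted over the list alone (adjusted p = 0.00176), and TOP2A fell by 0.40 ± 0.06 and 0.34 ± 0.06. Of 17 MYC-repressed genes 7 fell and 1 rose in shCTR9 cells, or 10 and 1 adjusted over the list alone (adjusted p = 0.00265). In shCDC73 cells 8 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.00299), and SPARC fell by 0.46 ± 0.06 and 0.45 ± 0.06. Of 7 osteoblast and mesenchymal markers 3 fell and 0 rose in shCTR9 cells, or 5 and 1 adjusted over the list alone (adjusted p = 0.0384, and adjusted p = 0.0621 with an estimated correlation). In shCDC73 cells 4 fell and 1 rose, or 5 and 1 adjusted over the list alone (adjusted p = 0.0289, and adjusted p = 0.0461 with an estimated correlation). Of 4 epithelial markers of other cells 3 fell in shCTR9 cells, also adjusted over the list alone (adjusted p = 0.0384, and adjusted p = 0.204 with an estimated correlation). The osteoblast call in shCTR9 cells ended without replicate 1 or 3 of every group (adjusted p = 0.0503 and adjusted p = 0.0772), and that in shCDC73 cells without replicate 3 (adjusted p = 0.0776). The epithelial call ended without replicate 1 or 4 of every group (adjusted p = 0.0669 and adjusted p = 0.0692), without the 3 libraries named above (adjusted p = 0.0787), with the transcript-length slope of each library as a covariate (adjusted p = 0.163) and with DESeq2 (adjusted p = 0.0516). Of the genes outside the lists, MISP, which acts on the mitotic spindle, fell by 1.34 ± 0.15 and 1.05 ± 0.15. In shCDC73 cells CDKN2C, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6, fell by 1.41 ± 0.16.

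In shCDC73 cells purine and pyrimidine synthesis rose with Dox, with 6 higher and 1 lower of 25, or 7 and 2 adjusted over the list alone (adjusted p = 0.0128). Replication-dependent histones fell there, with 0 higher and 4 lower of 12, or 0 and 5 adjusted over the list alone (adjusted p = 0.00143). Glycolysis genes passed there with 5 higher and 2 lower of 23, also adjusted over the list alone (adjusted p = 0.0242, and adjusted p = 0.174 with an estimated correlation), but not without replicate 1 of every group (adjusted p = 0.0722). Common MYC targets passed in shCTR9 and shCDC73 cells (adjusted p = 0.00352 and adjusted p = 2.81e-06), but gave adjusted p = 0.327 and adjusted p = 0.0708 with an estimated correlation. Cytoplasmic ribosomal proteins had medians of -0.16 and -0.14 (adjusted p = 0.00893 and adjusted p = 0.0252), or adjusted p = 0.814 and adjusted p = 0.798 with an estimated correlation. These moved with the 3 libraries named above. Without them the medians were -0.030 (adjusted p = 0.396) and 0.110 (adjusted p = 0.00957), a change of direction in shCDC73 cells. With the transcript-length slope of each library as a covariate both changed direction, to 0.073 (adjusted p = 0.025) and 0.077 (adjusted p = 0.0211). The calls also ended in shCTR9 cells without replicate 1 of every group (adjusted p = 0.406) and in shCDC73 cells without replicate 3 (adjusted p = 0.371). In all, Dox raised 1167 and lowered 1137 genes in shCTR9 cells, and raised 1167 and lowered 1035 in shCDC73 cells. With hairpin 3 or 5 against CTR9 alone the counts were 1186 and 860, and with hairpin 3 against CDC73 alone 881. Without replicate 3 or 4 of every group the count in shCDC73 cells was 1385 or 1422, and in shCTR9 cells it was 1467 without replicate 4.

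Lowering CTR9 or CDC73 in EtOH asks what these subunits did while the inducible MYC gene was not switched on. Genes of the p53 response and immediate early genes rose in both knockdowns (8 libraries against 4). Of 29 p53 targets 15 rose and 2 fell in shCTR9 cells (adjusted p = 4.74e-05), and 14 rose and 4 fell in shCDC73 cells (adjusted p = 0.000145), with the same counts adjusted over the list alone. CDKN1A, the cell cycle inhibitor p21, rose by 0.73 ± 0.07 and 0.91 ± 0.07 in shCTR9 and shCDC73 cells. The kinase gene PLK3 rose by 2.11 ± 0.13 and 2.19 ± 0.13 and SESN2 by 1.22 ± 0.10 and 1.16 ± 0.10. Of 19 immediate early genes 11 rose and 1 fell in shCTR9 cells, or 12 and 1 adjusted over the list alone (adjusted p = 7.45e-07). In shCDC73 cells 15 rose and 2 fell, also adjusted over the list alone (adjusted p = 3.47e-07). FOS rose by 2.58 ± 0.22 and 2.85 ± 0.21 and ATF3 by 1.75 ± 0.11 and 1.57 ± 0.12. Among single genes with large changes, UCA1, a long noncoding RNA, rose by 4.00 ± 0.33 and 3.76 ± 0.34. BIRC3, an inhibitor of apoptosis, fell by 2.12 ± 0.13 and 2.27 ± 0.13, and TRAF1, a signalling adaptor gene, fell by 2.16 ± 0.16 and 2.13 ± 0.15. HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose by 1.41 ± 0.09 and 2.01 ± 0.09.

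Genes of DNA replication, double-strand break repair, tRNA charging and nucleotide synthesis fell in EtOH. Of 40 DNA replication and E2F targets 25 fell and 4 rose in shCTR9 cells, or 27 and 4 adjusted over the list alone (adjusted p = 2.43e-07). In shCDC73 cells 20 fell and 6 rose, also adjusted over the list alone (adjusted p = 0.000146). E2F2 fell by 1.97 ± 0.13 and 1.96 ± 0.13 and the helicase gene MCM6 by 1.34 ± 0.10 and 1.19 ± 0.10. Of 38 double-strand break repair genes 20 fell and 3 rose in shCTR9 cells, also adjusted over the list alone (adjusted p = 0.00137). In shCDC73 cells 22 fell and 4 rose, or 24 and 4 adjusted over the list alone (adjusted p = 0.00016). BRCA1 fell by 1.28 ± 0.10 and 1.21 ± 0.10 and RAD50 by 1.23 ± 0.12 and 1.02 ± 0.11, while H2AX, a histone gene of the same list, rose by 0.94 ± 0.10 in shCDC73 cells. Of 20 aminoacyl-tRNA synthetases 10 fell and 2 rose in shCTR9 cells, also adjusted over the list alone (adjusted p = 0.00189). In shCDC73 cells 11 fell and 2 rose, or 12 and 2 adjusted over the list alone (adjusted p = 0.000142), and AARS1 fell by 1.11 ± 0.08 and 1.17 ± 0.08. Of 25 purine and pyrimidine synthesis genes 12 fell and 2 rose in shCTR9 cells, also adjusted over the list alone (adjusted p = 0.00272). In shCDC73 cells 13 fell and 4 rose, or 14 and 4 adjusted over the list alone (adjusted p = 0.000664), and PAICS fell by 0.84 ± 0.05 and 0.96 ± 0.05. Of 34 G2 and M phase genes 14 fell and 1 rose in shCTR9 cells, or 15 and 1 adjusted over the list alone (adjusted p = 0.00256). In shCDC73 cells 17 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.00016), and the spindle factor gene TPX2 fell by 0.68 ± 0.07 and 0.79 ± 0.07.

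Replication-dependent histones, most of whose transcripts lack a poly(A) tail, rose in shCDC73 cells in EtOH. There 9 rose and 1 fell of 12, or 10 and 2 adjusted over the list alone (adjusted p = 7.38e-06), with H2AC11 at 2.44 ± 0.13. In shCTR9 cells 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (adjusted p = 0.00189, and adjusted p = 0.066 with an estimated correlation). Of 30 TGF-beta, matrix and cytoskeleton genes 19 fell and 4 rose in shCTR9 cells, also adjusted over the list alone (adjusted p = 0.00193, and adjusted p = 0.101 with an estimated correlation). In shCDC73 cells 17 fell and 6 rose, or 19 and 6 adjusted over the list alone (adjusted p = 0.0282, and adjusted p = 0.287 with an estimated correlation). THBS1 fell by 1.64 ± 0.12 and 1.67 ± 0.12 while CCN2 rose by 1.74 ± 0.14 and 2.00 ± 0.14. Of 42 common MYC targets 19 fell and 5 rose in shCTR9 cells and 21 fell and 6 rose in shCDC73 cells, also adjusted over the list alone (adjusted p = 0.00189 and adjusted p = 0.00167). With an estimated correlation these gave adjusted p = 0.302 and adjusted p = 0.313. Ribosome biogenesis did not pass, with 17 higher and 4 lower in shCTR9 cells (adjusted p = 0.265) and 16 and 13 in shCDC73 cells (adjusted p = 0.729). In all, 2919 genes rose and 2810 fell in shCTR9 cells, and 3060 rose and 3095 fell in shCDC73 cells. The matrix call in shCDC73 cells ended without the 3 libraries named above (adjusted p = 0.0692, over alternatives from 0.00019 to 0.0692), which are all from knockdown cells in EtOH.

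With MYC switched on, p53 targets and immediate early genes were again higher in both knockdowns (8 libraries against 4). Of 29 p53 targets 15 rose and 2 fell in shCTR9 cells (adjusted p = 8.81e-06) and 15 rose and 3 fell in shCDC73 cells (adjusted p = 1.27e-05), with the same counts adjusted over the list alone. The kinase gene PLK2 rose by 1.59 ± 0.08 and 1.82 ± 0.08 and CDKN1A by 0.89 ± 0.07 and 1.08 ± 0.07 in shCTR9 and shCDC73 cells. Of 19 immediate early genes 11 rose and 3 fell in shCTR9 cells, or 12 and 3 adjusted over the list alone (adjusted p = 6.96e-05). In shCDC73 cells 13 rose and 3 fell, also adjusted over the list alone (adjusted p = 1.27e-05), and IER3 rose by 2.04 ± 0.16 and 2.32 ± 0.16. Of 20 aminoacyl-tRNA synthetases 13 fell and 2 rose in shCTR9 cells, or 14 and 2 adjusted over the list alone (adjusted p = 3.95e-05). In shCDC73 cells 12 fell and 3 rose, also adjusted over the list alone (adjusted p = 1.84e-05), and FARSB fell by 1.55 ± 0.12 and 1.17 ± 0.12. Of 25 purine and pyrimidine synthesis genes 15 fell and 4 rose in shCTR9 cells (adjusted p = 0.00269) and 15 fell and 5 rose in shCDC73 cells (adjusted p = 0.0054), also adjusted over the list alone. RRM2 of the same list rose by 0.89 ± 0.07 and 1.11 ± 0.07. In shCDC73 cells 10 of 22 cholesterol synthesis genes rose and 1 fell, or 10 and 2 adjusted over the list alone (adjusted p = 0.00725). SQLE, an enzyme gene of that pathway, rose there by 0.85 ± 0.07.

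Repair and replication genes were lower in Dox as well. Of 38 double-strand break repair genes 23 fell and 2 rose in shCDC73 cells, or 23 and 3 adjusted over the list alone (adjusted p = 0.000257). In shCTR9 cells 19 fell and 3 rose, or 20 and 3 adjusted over the list alone (adjusted p = 0.00149, and adjusted p = 0.0647 with an estimated correlation), and BRCA1 fell by 1.14 ± 0.11 in both. Of 40 DNA replication and E2F targets 19 fell and 7 rose in shCTR9 cells, or 19 and 8 adjusted over the list alone (adjusted p = 0.00059), with E2F2 at -1.98 ± 0.15. In shCDC73 cells 18 fell and 9 rose, or 19 and 10 adjusted over the list alone (adjusted p = 0.0493, and adjusted p = 0.0852 with an estimated correlation). That call ended without replicate 1 (adjusted p = 0.061) or 3 (adjusted p = 0.0589) of every group and without the 3 libraries named above (adjusted p = 0.0575). It also ended with a replicate block (adjusted p = 0.0547), over alternatives from 0.001 to 0.0807. PRIM1, a primase subunit gene, fell by 1.95 ± 0.17 in shCDC73 cells, and BIRC3 by 2.05 ± 0.14 and 2.28 ± 0.15 in shCTR9 and shCDC73 cells.

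Common MYC targets were lower in Dox, with 21 that fell and 7 that rose of 42 in shCTR9 cells, or 23 and 7 adjusted over the list alone (adjusted p = 0.000234). In shCDC73 cells 19 fell and 8 rose, or 22 and 9 adjusted over the list alone (adjusted p = 0.0054). With an estimated correlation these gave adjusted p = 0.271 and adjusted p = 0.35. CCND2 fell by 1.11 ± 0.06 and 0.95 ± 0.06. In shCDC73 cells 12 mitochondrial ribosomal protein genes fell and 1 rose of 35, or 11 and 1 adjusted over the list alone (adjusted p = 0.0054, and adjusted p = 0.469 with an estimated correlation). Among histones 5 rose and 3 fell of 12 there, or 6 and 3 adjusted over the list alone (adjusted p = 0.0123, and adjusted p = 0.172 with an estimated correlation). With limma-voom the histone call ended (adjusted p = 0.0954, over alternatives from 0.00468 to 0.0954). G2 and M phase genes did not pass in Dox, with 8 that rose and 9 that fell in shCTR9 cells (adjusted p = 0.784) and 4 and 10 in shCDC73 cells (adjusted p = 0.324). Nor did matrix genes, with 5 and 9 (adjusted p = 0.662) and 6 and 10 (adjusted p = 0.786). In all, 2654 genes rose and 2592 fell in shCTR9 cells in Dox, and 2791 rose and 2850 fell in shCDC73 cells. With hairpin 4 against CDC73 alone the count was 3670.

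**Figure D3:**
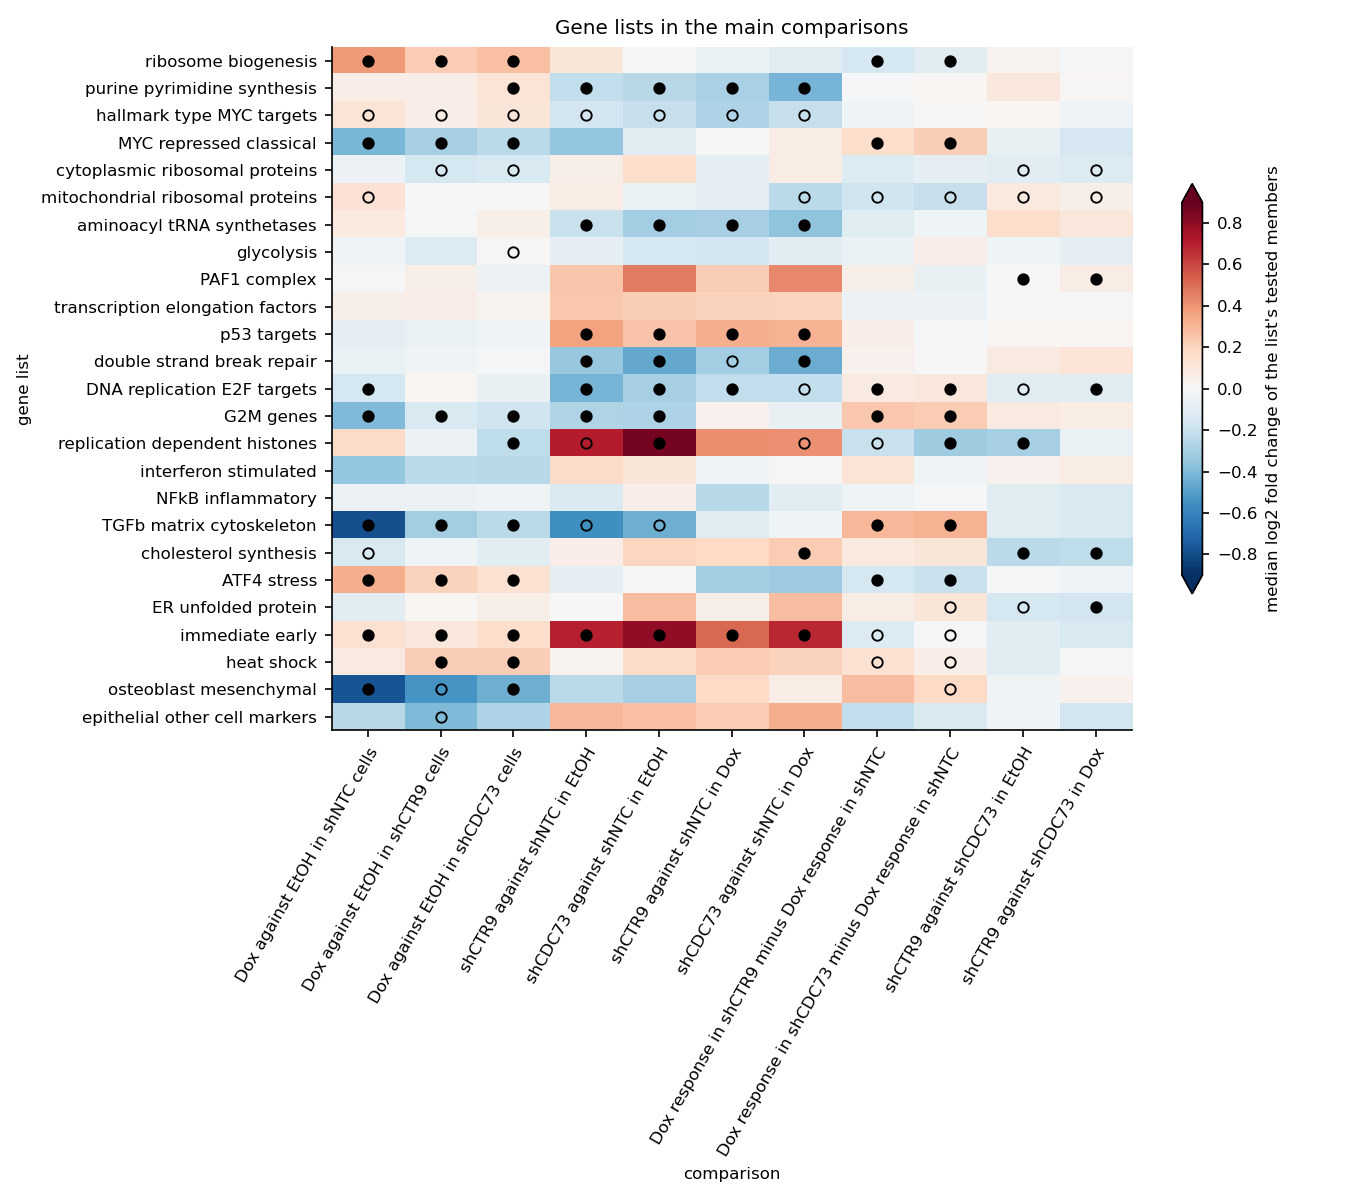
Median log2 fold change of the tested members of each gene list (colour) in the first 11 comparisons, where filled dots mark lists with an adjusted p under 0.05 both with the preset and with an estimated correlation, and open dots those that pass with the preset correlation only. In EtOH the immediate early list had medians of 0.70 in shCTR9 and 0.80 in shCDC73 cells, and the DNA replication and E2F list of -0.42 and -0.30.

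The knockdowns of CTR9 and CDC73 were then set side by side, gene by gene. In EtOH 2274 genes were higher in both, where 711.3 would fall in both lists if these were independent. Likewise 2302 were lower in both (692.6 if independent) and 12 moved in opposite directions. In Dox 2120 were higher in both (589.9 if independent), 2111 lower in both (588.3) and 6 opposite. Across genes, which are not independent replicates, Pearson's r was 0.908 in EtOH and 0.923 in Dox, and Spearman's rho 0.879 and 0.884. In simulations of unchanged groups the shared shNTC libraries gave r = 0.651 and 0.647, with covariances of 0.0345 and 0.0359 against the measured 0.4005 and 0.4081. With different shNTC libraries for each knockdown r lay between 0.779 and 0.800 in EtOH and between 0.785 and 0.802 in Dox. All shNTC cells carry the same control hairpin, so a trait of those cells would enter the changes of both knockdowns alike. Neither the simulations nor the splits remove it.

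**Figure D4:**
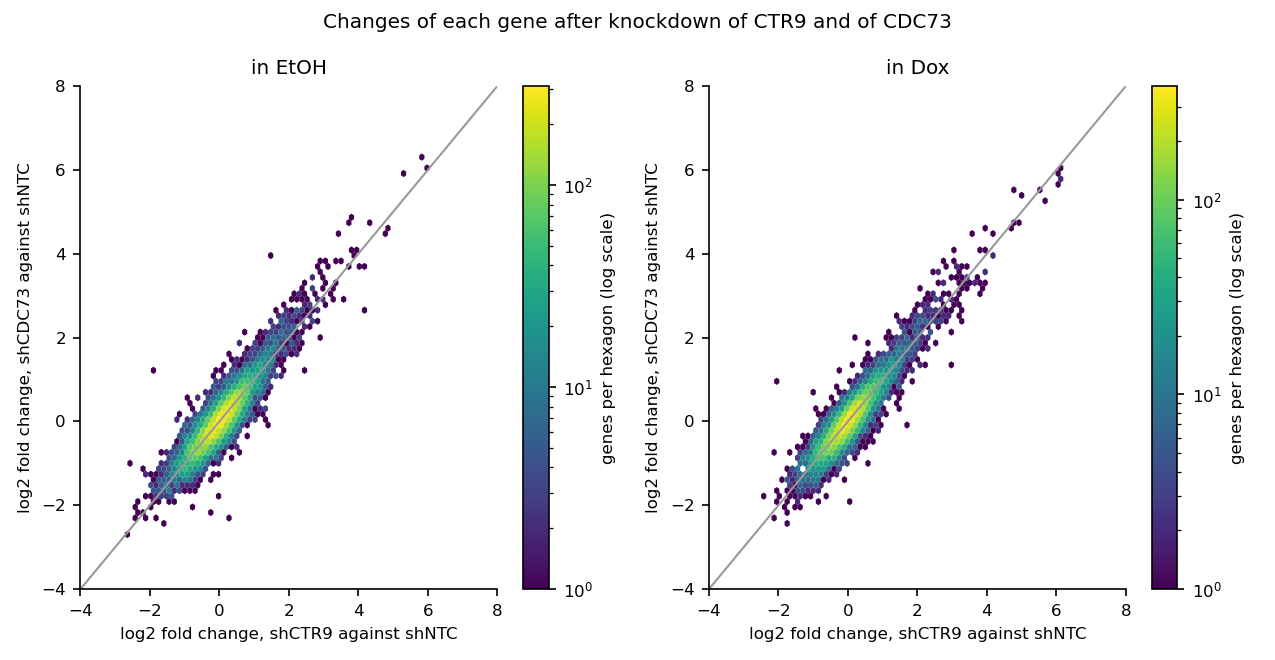
Log2 fold change of each tested gene against shNTC with shCTR9 (horizontal) and shCDC73 (vertical), in EtOH and in Dox, where colour gives the number of genes per hexagon on a log scale and the line marks equal changes. The correlation across genes was 0.908 in EtOH and 0.923 in Dox, beside 0.651 and 0.647 in simulations where only the controls were shared.

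Whether the knockdowns altered the response to Dox was tested as the difference between Dox responses (16 knockdown libraries and 8 of shNTC). RRM2, which fell with Dox in shNTC cells, had a response higher by 0.77 ± 0.09 in shCTR9 (adjusted p = 3.13e-07) and by 0.74 ± 0.09 in shCDC73 cells (adjusted p = 1e-06). The p53 target PLK2 differed by 0.83 ± 0.11 (adjusted p = 1.59e-06) and 0.97 ± 0.11 (adjusted p = 3.19e-08). In shCDC73 cells EGR1 differed by -1.59 ± 0.22 (adjusted p = 6.81e-06). In shCTR9 cells the noncoding RNA LINC00452 differed by 1.99 ± 0.24 (adjusted p = 3.13e-07). The lists below are given for their own difference, which shares its shNTC libraries with the Dox response of shNTC cells, so noise in those moves the pair in opposite directions. For G2 and M phase genes the median difference was 0.24 in shCTR9 cells, where 1 member was called higher and 0 lower, or 6 and 0 adjusted over the list alone (adjusted p = 2.43e-08). In shCDC73 cells it was 0.23, with 1 and 0, or 2 and 0 adjusted over the list alone (adjusted p = 8.69e-09). For matrix and cytoskeleton genes it was 0.30 in shCTR9 cells, with 2 and 0, or 3 and 0 adjusted over the list alone (adjusted p = 2.81e-07). In shCDC73 cells it was 0.31, with 2 and 0, or 6 and 0 adjusted over the list alone (adjusted p = 1.07e-08). No group received Dox without the inducible gene, and MYC in Dox stood at 55.5% to 77.4% of the shNTC level in the knockdowns, so an altered response is not separated from a lower MYC level.

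More lists differed in their response. DNA replication and E2F targets had median differences of 0.08 and 0.10 (adjusted p = 0.000324 and adjusted p = 0.000108), with 3 members higher and 0 lower in each knockdown, also adjusted over the list alone. MYC-repressed genes had 0.16 in shCTR9 and 0.22 in shCDC73 cells (adjusted p = 0.00262 and adjusted p = 0.000998). Adjusted over the list alone 1 and 2 members were called higher. Ribosome biogenesis, which rose with Dox, had a median difference of -0.16 in shCTR9 cells (adjusted p = 6.25e-06) and -0.10 in shCDC73 cells (adjusted p = 0.00466). The latter call ended without replicate 2 of every group (adjusted p = 0.0501, over alternatives from 2.99e-06 to 0.0501). ATF4 targets had -0.16 and -0.20 (adjusted p = 0.000684 and adjusted p = 0.000423), with 0 higher and 1 lower in each, or 0 and 4 adjusted over the list alone. Histones had -0.20 in shCTR9 cells (adjusted p = 0.0204, and adjusted p = 0.166 with an estimated correlation) and -0.32 in shCDC73 cells (adjusted p = 9.16e-06), with 0 and 5 lower adjusted over the list alone. The call in shCTR9 cells ended with the covariate (adjusted p = 0.0985) and without replicate 1 or 2 of every group (adjusted p = 0.105 and adjusted p = 0.0596). Heat shock genes passed in shCTR9 cells with 2 higher and 0 lower, or 5 and 0 adjusted over the list alone (adjusted p = 0.000684, and adjusted p = 0.116 with an estimated correlation). In shCDC73 cells 0 members were called, or 3 higher and 0 lower adjusted over the list alone (adjusted p = 0.0251, and adjusted p = 0.285 with an estimated correlation). That call ended without replicate 1 or 4 of every group (adjusted p = 0.0606 and adjusted p = 0.203) and with libraries sharing a letter summed (adjusted p = 0.061). Immediate early genes passed with medians of -0.12 and -0.02 (adjusted p = 0.0262 and adjusted p = 0.0294, or adjusted p = 0.121 and adjusted p = 0.142 with an estimated correlation). Both calls ended without replicate 1 of every group (adjusted p = 0.0984 and adjusted p = 0.0718) or replicate 4 (adjusted p = 0.273 and adjusted p = 0.217), among other settings. In shCDC73 cells the unfolded protein response (adjusted p = 0.0495) and osteoblast markers (adjusted p = 0.0448) also passed, but gave adjusted p = 0.221 and adjusted p = 0.0711 with an estimated correlation. Both of these ended without replicate 2 of every group (adjusted p = 0.0727 and adjusted p = 0.117) or replicate 4 (adjusted p = 0.237 and adjusted p = 0.215), among other settings. Mitochondrial ribosomal proteins passed in both (adjusted p = 0.00342 and adjusted p = 0.00389), but gave adjusted p = 0.515 and adjusted p = 0.45 with an estimated correlation. That call ended without replicate 1 of every group in shCTR9 cells (adjusted p = 0.0984) and without the 3 libraries named above in shCDC73 cells (adjusted p = 0.759). With the covariate it ended in both (adjusted p = 0.23 and adjusted p = 0.107).

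The difference in response was called for 75 genes in shCTR9 cells (50 higher, 25 lower) and for 59 in shCDC73 cells (40 higher, 19 lower). These counts moved in both directions with the setting. They were 294 and 235 with the transcript-length slope of each library as a covariate, 197 and 129 with limma-voom and 131 and 93 with a replicate block. In shCTR9 cells they were 46 and 36 without Dox shNTC replicate 1 and 4, and 42 and 38 without EtOH shNTC replicate 3 and 4. In shCDC73 cells they were 38 without Dox shCDC73 hairpin 3 replicate 4, 39 without Dox shCDC73 hairpin 4 replicate 4 and 38 without EtOH shCDC73 hairpin 4 replicate 1. They were 27, 39 and 30 without Dox shNTC replicate 2, 3 and 4, and 25 without EtOH shNTC replicate 3 and also without replicate 4. Without replicate 1, 2, 3 or 4 of every group they were 35, 17, 17 and 9 in shCTR9 cells and 33, 14, 15 and 10 in shCDC73 cells. Without the 3 libraries named above the counts were 156 and 116.

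Over all genes induced or repressed by Dox, the size of the shift depended on how the genes were chosen. They were first chosen in the other knockdown, whose libraries are not in the contrast. This choice favours genes that keep their response after a knockdown, so it can miss a weakening both knockdowns share. The 1035 genes repressed by Dox had a median difference of 0.063 in shCTR9 cells (fry adjusted p = 0.00119 over the 4 tests), with a median response of -0.446 in shNTC and -0.383 in shCTR9 cells. In shCDC73 cells 1137 such genes had a median difference of 0.043 (fry adjusted p = 0.0234, but camera adjusted p = 0.0575 with an estimated correlation), which with hairpin 4 alone was -0.008. The 1167 induced genes of each test did not pass, with median differences of -0.052 in shCTR9 (fry adjusted p = 0.23) and -0.041 in shCDC73 cells (fry adjusted p = 0.345). Where libraries were left out, the call was read at an unadjusted fry p of 0.05. Without replicate 2 of every group repressed genes no longer passed in shCTR9 cells (median 0.035). Nor did they in shCDC73 cells without replicate 2, 3 or 4 (0.032, 0.061 and 0.048). With genes chosen in 2 shNTC libraries per treatment and tested against the other 2, all 4 sets passed. Repressed genes had medians of 0.267 in shCTR9 and 0.285 in shCDC73 cells, and induced genes -0.202 and -0.176. That choice favours genes responding more in shNTC cells and can overstate a weakening. Induced genes chosen in the other knockdown passed without the 3 libraries named above (-0.082 and -0.073) and without replicate 1 of every group (-0.075 and -0.066).

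The knockdowns were also compared with each other (8 libraries against 8), where values above 0 are higher in shCTR9 cells. Cholesterol synthesis genes were lower in shCTR9 cells in EtOH, with 8 lower and 0 higher of 22, or 10 and 1 adjusted over the list alone (adjusted p = 0.000146). In Dox the counts were 8 and 0, also adjusted over the list alone (adjusted p = 0.000126), and SQLE differed by -0.39 ± 0.06 and -0.32 ± 0.06. Genes of the unfolded protein response were lower in EtOH, with 5 and 0 of 20, or 9 and 1 adjusted over the list alone (adjusted p = 0.00162, and adjusted p = 0.051 with an estimated correlation). In Dox the counts were 5 and 0, or 6 and 0 adjusted over the list alone (adjusted p = 0.000315), with the chaperone gene HSPA5 at -0.39 ± 0.05 and -0.41 ± 0.05. Histones were lower in EtOH, with 4 and 0 of 12, or 5 and 0 adjusted over the list alone (adjusted p = 0.000146), and H2AC11 at -0.71 ± 0.08. DNA replication and E2F targets were lower in Dox, with 10 lower and 1 higher of 40, or 12 and 2 adjusted over the list alone (adjusted p = 0.0111). In EtOH it was 12 and 2, also adjusted over the list alone (adjusted p = 0.0351, and adjusted p = 0.051 with an estimated correlation), but the call ended without the 3 libraries named above (adjusted p = 0.0634) and without replicate 2 of every group (adjusted p = 0.0596). HEXIM1 differed by -0.60 ± 0.06 and -0.58 ± 0.06 in EtOH and Dox. The tRNA methyltransferase gene METTL1 in EtOH was higher by 1.03 ± 0.15 and GATC, of the mitochondrial glutamyl-tRNA amidotransferase, in Dox by 0.88 ± 0.09. The PAF1 complex list, which holds both targets, passed in EtOH and Dox (adjusted p = 0.000146 and adjusted p = 0.00112). It did not pass without the filter on low counts (adjusted p = 0.136 and adjusted p = 0.411) or with limma-voom (adjusted p = 0.261 and adjusted p = 0.4).

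In EtOH 1047 genes were higher and 828 lower in shCTR9 than in shCDC73 cells, and in Dox 714 were higher and 584 lower. Fitted with these groups alone the counts were 1011 and 1963. Without replicate 2, 3 or 4 of every group they were 1022, 1154 and 922 in EtOH and 715, 692 and 498 in Dox. Cytoplasmic ribosomal proteins had medians of -0.10 in EtOH (adjusted p = 0.0425) and -0.12 in Dox (adjusted p = 0.00303), or adjusted p = 0.756 and adjusted p = 0.649 with an estimated correlation. Mitochondrial ribosomal proteins had 0.09 and 0.05 (adjusted p = 0.0448 and adjusted p = 0.0337), or adjusted p = 0.611 and adjusted p = 0.624 with an estimated correlation. Both calls ended without replicate 2 of every group (adjusted p = 0.0631 and adjusted p = 0.0655), and that in EtOH also without replicate 1 or 4 (adjusted p = 0.175 and adjusted p = 0.076). For cytoplasmic ribosomal proteins in EtOH the median was 0.001 without the 3 libraries named above (adjusted p = 0.835) and 0.007 without replicate 3 of every group (adjusted p = 0.952).

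Hairpins against the same gene were compared last (4 libraries against 4), since effects of a hairpin beyond its target would differ between them. CDC73 hairpins 4 and 3 differed in 3920 genes in EtOH (2060 higher and 1860 lower with hairpin 4) and in 1628 in Dox (736 higher and 892 lower). CDC73 itself differed by 0.01 ± 0.31 in EtOH and 0.49 ± 0.33 in Dox (adjusted p = 0.373). MYC was lower with hairpin 4 by -0.35 ± 0.08 in EtOH (adjusted p = 0.00048) and -0.37 ± 0.07 in Dox (adjusted p = 0.000301). With only the groups compared the MYC call in EtOH ended (adjusted p = 0.0598, over alternatives from 4.87e-05 to 0.0598). CTR9 was lower with hairpin 4 in Dox by -0.49 ± 0.10 (adjusted p = 0.000301). The libraries of hairpin 4 in EtOH include replicates 1 and 3, named above for transcript length, and without these the count in EtOH was 1952. Without replicate 3 of every group it was 1980, and in Dox it was 867, 978 and 957 without replicate 2, 3 and 4 of every group.

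CTR9 hairpins 5 and 3 differed in 74 genes in EtOH (22 higher and 52 lower with hairpin 5) and in 35 in Dox (11 higher and 24 lower). Fitted on those 8 libraries alone edgeR called 0 genes in EtOH, with 1122 at an unadjusted p under 0.05. With all libraries limma-voom called 121 and DESeq2 96. In Dox the fit on the 8 libraries called 100. Without EtOH shCTR9 hairpin 3 replicate 1, 2 or 3 the count in EtOH was 41, 115 or 49, and without hairpin 5 replicate 2, 3 or 4 it was 23, 40 or 35. In Dox it lay between 9 and 18 without any one of the 8 libraries. Without replicate 1, 2, 3 or 4 of every group the counts were 28, 25, 13 and 19 in EtOH and 13, 5, 6 and 5 in Dox. Against shNTC in EtOH the genes that passed with each hairpin alone in the same direction numbered 3728 for CTR9 and 3480 for CDC73, and those in opposite directions 0 and 47. Both hairpins stand against the same shNTC libraries, which raises the number in the same direction.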

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

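The tests of the difference between Dox responses were planned, while the split tests given with them were chosen after first results had been seen. The Dox response differed from that of shNTC cells for 75 genes in shCTR9 cells and for 59 in shCDC73 cells. Of 100 splits of the Dox libraries 1, the real one, gave as many genes in either case. For shCTR9 it gave 78 genes, in a fit of these groups with 1 Dox response per knockdown, and another split at most 1. For shCDC73 it gave 26, and another split at most 7. Other splits mix libraries within each hairpin, unlike the real grouping, so these counts do not exclude a random grouping.

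Single libraries stood apart from the other 3 of their group in 4 of 100 groups of values tested, where chance gives about 1 in 20. SKIC8 stood at 31.6 CPM in Dox shCDC73 hairpin 3 replicate 3, against 38.1 to 38.6 in the others. LEO1 stood at 13 CPM in EtOH shCDC73 hairpin 3 replicate 4, against 6.66 to 7.14 in the others. The slope on transcript length was -0.025 in Dox shCTR9 hairpin 5 replicate 1, against 0.026 to 0.032, and -0.037 in EtOH shCTR9 hairpin 5 replicate 1, against 0.009 to 0.013.

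The difference between the hairpins against CDC73 in EtOH was weighed against the pair of hairpin 4 libraries that stand apart on transcript length, replicates 1 and 3. Without these 1952 genes were called (950 higher and 1002 lower with hairpin 4), and without replicates 2 and 4 of that hairpin 5189, so part of the 3920 calls may rest on those libraries. A lasting difference between the hairpins is also consistent with the data, since across genes the difference in EtOH without those libraries correlated with that in Dox at r = 0.653 (Spearman's rho 0.638), where no library of hairpin 4 stands apart. With all libraries r was 0.574, and 1650 genes were called in the same direction with and without them. The CDC73 transcript stood at 22.6% and 23.0% of shNTC with hairpins 3 and 4 in EtOH, a difference of 0.01 ± 0.31, while protein levels and effects beyond the target were not tested.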

How the results depend on the processing

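The fits without the 3 libraries that stand apart on transcript length and with the transcript-length slope of each library as a covariate were chosen after the data had been seen, and all other settings were planned. The counts of genes for both knockdowns against shNTC in EtOH and for shCTR9 against shNTC in Dox stayed within 1.5 times of those reported under every setting. For shCDC73 in Dox this failed with hairpin 4 alone (3670), where 4 libraries stand against 4. With hairpin 3 or 5 alone Dox called 1186 or 860 genes in shCTR9 cells, and with hairpin 3 alone 881 in shCDC73 cells. The count of list calls, 107, lay between 96 and 145 under the settings tried.

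Other counts moved by more than 1.5 times. With the covariate Dox called 3405 genes in shNTC and 3317 in shCDC73 cells, and the differences of response 294 and 235 in shCTR9 and shCDC73 cells. The covariate gave 3150 and 2570 genes between the knockdowns in EtOH and Dox, 255 and 206 between CTR9 hairpins, and 2852 between CDC73 hairpins in Dox. Without the 3 libraries that stand apart the differences of response gave 156 and 116, the knockdowns in Dox 2062, CTR9 hairpins in Dox 92 and CDC73 hairpins in EtOH 2495. With limma-voom they gave 197 and 129, the knockdowns in Dox 1998 and CTR9 hairpins 121 and 102. With only the groups compared the difference of response gave 27 in shCDC73 cells, the knockdowns 1011 and 1963, CTR9 hairpins 0 and 100 and CDC73 hairpins in EtOH 2171. The difference of response gave 35 and 19 with shCTR9 hairpins 3 and 5 alone, and in shCDC73 cells 10 with hairpin 4 alone and 37 with a mean of at least 1 CPM. CTR9 hairpins in EtOH gave 206 with libraries sharing a letter summed. The causes were not tested, except that fits of single hairpins or of fewer groups hold fewer libraries.

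Leaving out each replicate number or library in turn gave 1303 to 1911 genes for Dox in shNTC, 1467 to 2367 in shCTR9 and 1385 to 2292 in shCDC73 cells. The differences of response ran from 9 to 80 in shCTR9 and from 10 to 74 in shCDC73 cells. Between the knockdowns it was 922 to 2048 in EtOH and 498 to 1275 in Dox, between CTR9 hairpins 13 to 115 and 5 to 18, and between CDC73 hairpins 1980 to 4301 and 867 to 1343.

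Replicate numbers were not taken to pair the libraries, since not every pair sharing a number correlated over 0.1. That rule does not exclude a batch shared by some of the libraries with the same number. The mean correlation of deviations over the 45 pairs sharing a number was 0.141, 0.074, 0.008 and 0.059 for numbers 1 to 4, with 23, 8, 1 and 10 pairs over 0.1, against -0.023 for pairs not sharing one. Of 40 libraries 28 correlated best with their own number, more than if each of the 4 numbers were equally likely. This is a hint, from the data and not the design, of a replicate effect that the main fit does not model. With a replicate block the differences of response gave 131 and 93 genes and CTR9 hairpins 183 and 54, and the list of DNA replication and E2F targets in shCDC73 against shNTC in Dox gave adjusted p = 0.0547. No other call of a list or a named gene ended with the block.

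Calls on the whole Dox response were read at an unadjusted fry p of 0.05. Induced genes in shCTR9 cells passed without the 3 libraries that stand apart (-0.082), with the covariate (-0.063), with limma-voom (-0.067) and with genes chosen in 2 shNTC libraries (-0.202), and leaving out libraries gave -0.075 to -0.027. Induced genes in shCDC73 cells passed in the same settings (-0.073, -0.053, -0.068 and -0.176) and with hairpin 3 alone (-0.109), with -0.069 to -0.009 when libraries were left out. Without passing, medians of induced genes lay above 0 with genes chosen at 1.5-fold (0.043 and 0.010) and with shCDC73 hairpin 4 alone (0.024). Repressed genes in shCTR9 cells did not pass without the filter (0.026), and left-out libraries gave 0.035 to 0.075. With genes chosen in 2 shNTC libraries, which can overstate a weakening, they passed (0.267, and 0.285 in shCDC73 cells). With limma-voom and hairpin 3 alone the latter passed at 0.075 and 0.107. In shCDC73 cells repressed genes did not pass without the filter (0.019), with a mean of at least 1 CPM (0.025), with libraries sharing a letter summed (0.030) or with genes chosen at 1.5-fold (0.081). There the median reversed with hairpin 4 alone (-0.008), and left-out libraries gave 0.032 to 0.067.

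The correlation of both knockdowns was 0.896 to 0.903 in EtOH and 0.913 to 0.919 in Dox without a replicate number, and at its lowest 0.779 and 0.785 with the shNTC libraries split. Of 1498 comparisons of list calls under other settings 1421 stayed, 72 ended and 5 reversed, and 82 of 107 calls stayed throughout. A reversal was read from the direction of the camera test, and all 5 were of cytoplasmic ribosomal proteins. By the sign of the median alone 15 lay on the other side of 0, in 7 of the calls. With Dox in shCTR9 cells the median was 0.073 with the covariate. With Dox in shCDC73 cells it was 0.077 with the covariate, 0.110 without the 3 libraries and 0.010 with limma-voom. Between the knockdowns in EtOH it was 0.001 without the 3 libraries. Of 4322 comparisons of named genes 4289 stayed, 29 ended, 4 passed anew and 0 reversed. Apart from MYC and the PAF1 complex subunits, these genes were named for their changes in the same data. That so many stayed was therefore partly fixed in advance. With these depths a 1.5-fold change was found for 28.4% of simulated genes in the comparison of 4 libraries with 4.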

Other observations

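The tests on cleavage-stage genes, the bound on the test of gene span and the split tests of knockdowns against shNTC, between knockdowns and of differences of response were chosen after results had been seen. As a sum over a list, genes active in the first divisions of the human embryo were higher in the knockdown cells, though not every member was. Of 33 genes in this list, many of them known targets of the transcription factor DUX4, 22 were tested. The list was added after some of its members had been seen. Only 2 of the 22, SNAI1 and RFPL4A, reach the count filter in the shNTC libraries alone, so counts of calls are no test of the pattern. These 2 were called higher against shNTC in both knockdowns, in EtOH and in Dox. In EtOH 11 of the 22 were called higher in each knockdown. RFPL1 and KHDC1L, which were not tested, stood at 0 CPM in every group. Summed over the list, CPM in Dox was 89.2 ± 10.9 in shNTC cells (SD, n = 4), 555 ± 20.1 and 543 ± 51.1 with shCTR9 hairpins 3 and 5, and 755 ± 54.7 and 449 ± 30.3 with shCDC73 hairpins 3 and 4. In EtOH the sums were 71.3 ± 11.2 in shNTC cells, 216 ± 28.5 and 162 ± 21.9 with shCTR9, and 303 ± 16.8 and 165 ± 15.7 with shCDC73. SNAI1 and RFPL4A carry much of these sums. Without these 2 members the sums in Dox were 28.0 ± 7.42 in shNTC cells, 277 ± 16.1 and 335 ± 55.3 with shCTR9, and 337 ± 44.9 and 269 ± 25.0 with shCDC73. In EtOH they were 22.3 ± 1.52 in shNTC cells, and the group means with the 4 hairpins lay between 55.0 and 78.5. Among members named after their values were seen, SNAI1 rose in Dox by 2.16 ± 0.12 in shCTR9 and 2.42 ± 0.12 in shCDC73 cells, from 32.7 ± 6.06 CPM. ZNF296 rose by 1.15 ± 0.24 and 1.40 ± 0.24, from 9.46 ± 3.90 CPM. DUX4 itself had 0 counts, but its absence was not tested.

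The 9 members without a close copy had a summed CPM, most of it from SNAI1, above the highest Dox shNTC library in 16 of the 16 Dox knockdown libraries. Reads shared between near-identical copies cannot account for that, but this says nothing of the members that have such copies. Of the 9, the 4 that did not reach the count filter gave 16 of 16 as well, with single members near or below the floor of 3 counts. Their summed CPM in Dox was 8.65 ± 3.45 and 11.7 ± 2.64 with shCTR9 hairpins 3 and 5, 5.77 ± 1.19 and 10.7 ± 1.75 with shCDC73 hairpins 3 and 4, and 0.203 ± 0.407 in shNTC cells (SD, n = 4). The sum over the whole list also lay above the highest Dox shNTC library in 16 of the 16, with or without SNAI1 and RFPL4A. The rise in these members was thus not confined to a few libraries. Since the list was added after some members had been seen to be higher, these counts were partly fixed in advance and are no independent test. Whether the rise with Dox was larger in knockdown cells than in shNTC cells stays open, since the fry p of the difference (1.02e-05, the larger of both knockdowns) comes from genes chosen after some had been seen to show it. Whether the loss of the PAF1 complex acts on these genes directly was not tested.

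Genes with a longer genomic span tended to be lower after knockdown, and those with a shorter span higher. Without adjustment, protein-coding genes under 10.5 kb had median changes from 0.14 to 0.26 against shNTC. Past 128 kb the median lay below that of genes from 65.1 to 128 kb only for shCTR9 in EtOH (-0.13 against -0.08). With transcript length, GC content, exon number and mean expression in the regression over 12316 genes, 8 of the 8 differences between a hairpin and shNTC in slope on log2 span lay below 0, and so did 8 of 8 without the 3 libraries that stand apart, so neither of these is likely to be the whole source. The mean difference was -0.013 (SE 0.003 over the 4 hairpins and 0.004 with the spread of the controls), against -0.014 to -0.058 for single hairpins without those terms. A shared effect of both knockdowns that follows span, in short or long genes, is compatible with this mean. With the labels of knockdown and shNTC libraries permuted within each treatment (100000 resamples, two-sided, 32 against 8 libraries) p was 0.0217, and 0.0237 without the 3 libraries (mean -0.009). This permutation exchanges single libraries and ignores that they are grouped by hairpin. Its p measures spread between libraries, not between hairpins. No single hairpin passed (smallest adjusted exact p = 0.229). All 4 hairpins are set against cells with 1 control hairpin, so a trait of those cells stays open.

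Splits of the same libraries into other groups were counted for each comparison, and real values are from fits of the groups compared in which the hairpins of a knockdown share 1 mean, or 1 Dox response. For Dox in shNTC cells 1 of 35 splits gave as many genes (3050 in the real one, at most 8 in another). For Dox in shCTR9 cells it was 1 of 100 (2168, at most 955) and in shCDC73 cells 1 of 100 (1674, at most 197). Against shNTC in EtOH it was 1 of 100 for shCTR9 (5206, at most 304) and for shCDC73 (4543, at most 0), and in Dox 1 of 100 for shCTR9 (5936, at most 67) and for shCDC73 (5421, at most 1). Between the knockdowns it was 1 of 100 in EtOH (420, at most 0) and in Dox (1091, at most 334). Between hairpins 4 and 3 against CDC73 it was 1 of 35 in EtOH (2171, at most 0) and in Dox (1988, at most 0), and between hairpins 5 and 3 against CTR9 it was 1 of 35 in Dox (100, at most 6). In these cases no other split that was tried gave as many genes. The splits exchange single libraries, while the libraries of a real group may not come from separate cultures. They therefore do not exclude that other groups of cells would differ as much. Between hairpins 5 and 3 against CTR9 in EtOH 35 of 35 splits gave as many, which a real count of 0 makes certain, so this says nothing about chance there.

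For the Dox response as a whole, 1 of 100 splits gave a median shift as large for induced genes in shCTR9 cells (-0.051, next 0.046) and for repressed genes there (0.066, next 0.043). For induced genes in shCDC73 cells 6 of 100 did (-0.052, highest other 0.124) and for repressed genes 15 of 100 (0.036, highest other -0.120). In shCTR9 cells the real grouping gave the largest shift, for induced genes by a narrow margin. Other splits mix libraries within each hairpin, which fixes the shift more tightly than the real grouping does, so their shifts spread less. These counts therefore do not exclude a random grouping in either knockdown. For induced genes in shCTR9 cells the test on genes chosen in the other knockdown did not pass (fry adjusted p = 0.23), so no shift of these is claimed.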
